A study of Homo sapiens with 4 samples.

How the data were processed

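Chromatin contacts of nascent and nuclear RNA were measured by GRID-seq in K562, a human leukaemia cell line that carries the BCR-ABL1 fusion. GRID-seq joins an RNA to the DNA it lies next to through a linker inside fixed nuclei, so that each sequenced molecule names an RNA and a place in the genome. Cells with wild-type RUNX1 (WT) and cells with the RUNX1 R320* change, a stop codon in the C-terminal part of this blood transcription factor, gave 2 libraries each, 4 in all. Per the labels' protocols, cells were fixed with 2 mM DSG for 45 minutes and then with 3% formaldehyde for 10 minutes at room temperature. Samples were grouped by the genotype in the labels. The labels do not say whether the libraries of a genotype came from separate cultures or whether the mutant cells were 1 clone or several.

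Per the submitters' processing notes, reads were handled with cutadapt 1.12, BWA and bedtools on the hg38 build. The authors deposited a table of 115357 connections, each a pair of an RNA and a regulatory element, with 1 score per genotype and a further score column that equals the R320* score minus the WT score in every row, within 1e-05. How the score was computed, whether it is on a log scale, and how the libraries of a genotype were combined are not given in the sources used here. In the deposited table a score is either 0 or above 1.2, and no connection is at 0 in both genotypes, so the table holds only connections that passed a minimum of 1.2 in WT, R320* or both. A score of 0 was therefore read as "not listed", never as a measured zero. The table types a connection as local, cis (the same chromosome) or trans (another chromosome), and each element as an active enhancer or active promoter with its nearest gene. Its elements come in a pair of blocks that share 0 elements: 20020 elements with a median length of 3081 bp, and 13928 with a median of 762 bp. What separates the blocks is not given in the sources used here.

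Values per library were not used here, since the table is pooled by genotype, so no replicate spread, p-value or test of the genotype could be had. Sequencing depth is unknown, and no interval that needs it is given. The design fixed before the data were examined allowed for this case: differences without a test, and named items ranked by size among those at or above the median of all items. It assumed a ratio scale, which the score does not have. Score differences of at least 1 unit, over the 52089 connections listed in both genotypes, therefore took the place of a 2-fold change. Genes and elements were compared by their number of listed connections, which has a true zero, in place of a summed value; both choices were made after the unit of the table was seen. Genes and elements listed in 1 genotype only were counted apart and have no ratio. The minimum was a mean over both genotypes of 25 connections per gene and of 2 RNAs per element. For single connections it was a mean score of 1.12, counting 0 as 0, which every connection listed in both genotypes passed.

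The rule for named items took the 12 genes with the largest log2 ratio of connection numbers in each direction, the 6 single connections with the largest score difference in each direction (1 per gene), the 3 elements with the largest log2 ratio in each direction, RUNX1, and up to 4 members per gene list by size of change. Where elements tied, the first in chromosome order was taken. Some genes that this rule takes are not reported here. Other named genes were chosen after their values were seen, and the text says so. Gene lists were fixed before the data were examined: erythroid, megakaryocytic, myeloid, stem and progenitor, RUNX1 and its partners, known RUNX1 targets, BCR-ABL, JAK and RAS signalling, cell cycle and growth, chromatin and looping, nuclear long noncoding RNA, lymphoid, non-blood and ribosomal protein genes. For a list with at least 3 members listed in both genotypes, the median log2 ratio was placed among 10000 random lists of the same size, matched on mean number of connections in 10 bins. This percentile describes these pooled values and is not a p-value.

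Gene positions came from a RefSeq gene table of GRCh38.p14, which shares the coordinates of hg38. Of 2637 RNA identifiers, 2497 matched by symbol, 70 of them through an older symbol, and 0 of those matched lay on another chromosome than the deposited table gives. Distance was taken from the nearest end of the gene to the element, because that table gives no strand; the planned distance from the gene's start could not be computed. Element starts were read as counting from 0 and are printed counting from 1. Genome balance was summed per chromosome and for cis contacts in 10 Mb windows with at least 100 connections.

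The gene comparison and the list percentile were tested on simulated data built from 2410 genes of the table. All 100 genes raised 4-fold that passed the minimum were called, as were the 48 of 100 lowered 4-fold that passed it, against 8 of 1060 unchanged genes. Of 200 lists with no shift, 3 fell outside the central 95%, and 195 of 200 shifted lists lay above it. The gene simulation covers counting error only and the lists were drawn with a set spread, so neither says anything of the spread between cultures. Alternatives covered the minimum, the size threshold, centring, the same chromosome alone and the score as gene value; leaving out chromosome 12, splitting the blocks and several others were added after the data were seen. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.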

Results

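GRID-seq was used to ask how contacts between RNAs and enhancers or promoters differ between K562 cells with wild-type RUNX1 (WT) and with RUNX1 R320*. There were 2 libraries per genotype, pooled by the authors into 1 score per connection and genotype. Values per library were not used here, so no difference below has a test, and SDs describe the spread over connections rather than over cultures. The table held 115357 connections between 2637 RNAs (2435 protein-coding, 202 long noncoding) and 33948 elements (23872 enhancers, 10076 promoters). WT listed 82454 connections and R320* 84992, with median scores of 1.71 and 1.73. Sequencing depth is unknown.

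RUNX1 itself (ENSG00000159216.18, chromosome 21, 34787801 to 35049302, hg38) had 16 connections in WT and 30 in R320* as an RNA, and 2 were shared. The median over RNAs of both genotypes was 28 in WT and 30 in R320*. The first shared connection was local, to an enhancer inside RUNX1 (chromosome 21, 34807759 to 34808130), with scores of 1.23 in WT and 1.32 in R320*. The other was trans, to an enhancer near the keratin gene KRT2 on chromosome 12 (52652733 to 52665026), with 1.55 and 1.67. Trans contacts made up 15 of the WT and 26 of the R320* connections of RUNX1 RNA. These lay on 6 chromosomes in WT and 9 in R320*, 12 in all. Several joined neighbouring elements, such as those at FAH in WT and TUBB1 in R320*, and are not independent. The mean of 23 connections for RUNX1 was below the minimum set for genes. Its local scores lay near the minimum of 1.2, against medians of 2.39 (WT) and 2.42 (R320*) for RNAs of both genotypes. The difference between 16 and 30 is therefore uncertain. The 14 elements nearest RUNX1 received 22 connections in WT and 15 in R320*, of which 7 were in both. The R320* change is not a deletion of the gene and RUNX1 RNA level was not measured, so these numbers do not check the genotype labels.

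Contacts close to the RNA's own gene were mostly listed in both genotypes, and distant ones mostly in 1. Of 5039 local connections 81.1% were in both genotypes, against 51.4% of 88442 cis and 11.5% of 21876 trans connections. Over all types, 52089 connections (45.2%) were in both, 32903 in R320* only and 30365 in WT only. Neighbouring elements share RNAs: with the connections of 1 RNA merged within 1 Mb, the balance turned, with 8072 in R320* only and 8462 in WT only. Trans contacts were more often in WT only (10276) than in R320* only (9076), but over RNAs listed in both genotypes the numbers were 9086 and 8918. Of all cis contacts, 19571 were in WT only and 23391 in R320* only. Enhancers and promoters differed little in the shared part, at 45.3% and 44.9%.

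The shared part fell with distance from the RNA's gene, and on the same chromosome so did the score. Median WT scores of shared connections were 2.19 under 100 kb, 1.78 up to 1 Mb, 1.55 beyond and 1.64 on other chromosomes. The trans value varied with the element's chromosome. It was 2.63 on chromosome 13, 2.25 on 11, 1.87 on 22 and 1.78 on 9, but 1.40 on 1, 1.46 on 6 and 1.43 on 7. Scores nearer the minimum of 1.2 can drop out of the list more easily, and this was not separated from distance. Under 100 kb, 80.5% of 17546 connections were in both genotypes; from 100 kb to 1 Mb, 61.1% of 42120; and over 1 Mb, 27.0% of 28319. A further 5496 connections on the gene's own chromosome belonged to RNAs without a position and were not placed. Median score differences over shared connections (R320* minus WT) were 0.0280 (SD 0.179) under 100 kb, 0.0577 (SD 0.268) up to 1 Mb and 0.0298 (SD 0.264) beyond. For contacts on another chromosome the median difference was -0.00403 (SD 0.279). The SDs are those of single connections. Centring on the overall median of 0.0394 turns the sign of the shortest and the longest cis bins, to -0.0115 and -0.00964.

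**Figure D1:**
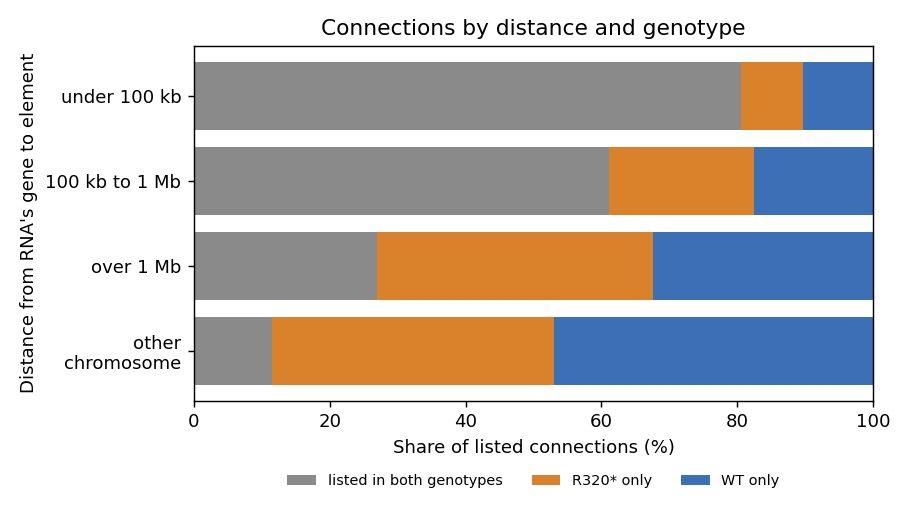
Stacked bars give the share of listed connections (percent, x axis) in both genotypes, in R320* only and in WT only, by distance between the RNA's gene and the element (y axis). The shared part goes from 80.5% under 100 kb to 11.5% on another chromosome.

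Where a connection was listed in both genotypes, its score was close in both. Part of this is built in, since a connection that fell below 1.2 counts as listed in 1 genotype only. Median scores of those listed in both were 1.83 in WT and 1.88 in R320*, so many could not fall by 1 unit and stay listed. The score difference had a median of 0.0394 and an SD of 0.247, and 95% of connections lay between -0.471 and 0.555. Scores correlated across connections (Pearson's r 0.875, Spearman's rho 0.814), which are not independent replicates. A difference of at least 1 unit was seen in 0.175% of the 52089, 52 higher in R320* and 39 lower. Centred on the median difference the counts were 38 and 49, so the balance between the directions rests on the scaling.

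Trans contacts between chromosomes 9, 13 and 22, with ABL1 on 9 and BCR on 22, were among those past 1 unit, in both directions. This set of chromosomes was not fixed before the data were examined, and the counts cover the whole chromosomes. None of the named connections lower in R320* is among them. Of the 15 trans connections past 1 unit, 9 joined chromosomes 9, 13 and 22, 5 of them higher in R320* and 4 lower; these chromosomes gave 416 of the 2524 shared trans connections, with a median difference of -0.0762 (SD 0.388). NUP214, a nuclear pore gene beside ABL1 on chromosome 9, contacted an enhancer near LINC00380 (chromosome 13, 91016988 to 91018239) with 1.34 in WT and 3.04 in R320*. BCR RNA contacted an enhancer inside GPC6 (chromosome 13, 93289940 to 93290828) with 1.34 and 3.03. DGCR2 of chromosome 22 contacted an enhancer inside ABL1 (chromosome 9, 130843738 to 130846794) with 1.42 and 2.86. Over all their shared trans connections, NUP214 had a median difference of -0.130 (SD 0.406, 133 connections) and ABL1 of -0.0393 (SD 0.297, 161), while BCR had 0.110 (SD 0.480, 25) and DGCR2 0.0919 (SD 0.686, 12). The other named higher ones were cis: PHF21A near its own gene (1.23 and 2.91), EFCAB2 on chromosome 1 (1.27 and 2.78), and the RNA-binding protein gene TIA1 at an ANXA4 enhancer (1.30 and 2.74).

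Among the lower ones, EEF1E1, an auxiliary factor of the tRNA synthetase complex, contacted an enhancer on chromosome 6 (8219241 to 8219569) with 4.13 in WT and 1.70 in R320*. The readthrough transcript EEF1E1-BLOC1S5 contacted the same element with 3.76 and 1.68; the gene models overlap, so the pair cannot be counted as separate findings. COQ8A, a gene of coenzyme Q synthesis, contacted a promoter at CDC42BPA (chromosome 1, 226990290 to 226990816) with 3.60 and 1.40. AC021087.5 of chromosome 5 contacted a chromosome 3 enhancer (197623217 to 197630278) with 3.56 and 1.38. RANBP3 had 3.09 and 1.26 at a chromosome 19 enhancer, and AGTRAP 3.34 and 1.56 at a promoter of C1orf167. Nearby connections of 1 RNA are not independent of each other.

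Among genes with a mean of at least 25 connections, the largest ratios were as follows. BTRC, a ubiquitin ligase subunit on chromosome 10 (101354048 to 101557313), had 7 connections in WT and 94 in R320* (log2 ratio 3.75), with 2 and 85 of them trans. SUGCT had 8 and 47 (2.55). HNRNPU, a nuclear matrix RNA-binding protein gene, had 44 and 103 (1.23), and its neighbour EFCAB2 34 and 73 (1.10). NCAM2 had 23 and 48, LINC01033 47 and 95, RNF157 28 and 56, WDR27 19 and 37, AC079466.1 17 and 33, AC007319.1 69 and 132, and PDE8A 34 and 65 connections.

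In the other direction, the noncoding AL713998.1 of chromosome 6 had 337 connections in WT and 25 in R320* (log2 ratio -3.75), with 316 and 13 of them trans. CCDC26, a noncoding gene at 8q24 (chromosome 8, 129351694 to 129680239), had 221 and 44 (-2.33). MIR3681HG had 42 and 17 (-1.30), and the imprinted noncoding gene MEG3 36 and 20 (-0.85). AC104170.1 (98 and 41), COLGALT2 (43 and 19) and FAM129A (86 and 42) all lie on chromosome 1, the last named pair within 1 Mb of each other. EP400 (41 and 17), RAP1B (42 and 19) and FBXW8 (40 and 22) lie on chromosome 12. VPS13B had 94 and 49 connections.

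Most genes had similar numbers. Of 1293 genes with a mean of at least 25 connections and listed in both genotypes, 757 had more in R320*, 471 fewer and 65 the same number. The median log2 ratio was 0.08, and 95% of genes lay between -0.62 and 0.71. Only 8 genes had at least 2-fold more and 8 at least 2-fold fewer, and these counts are small: with same-chromosome contacts alone they were 4 and 5, and without the minimum 72 and 34. In the simulation, counting error alone put 8 of 1060 unchanged genes at 2-fold in either direction. Ratios near 2-fold may therefore be no more than counting error. The RNAs with most connections, named after their values were seen, included the nuclear speckle and paraspeckle RNAs MALAT1 (670 in WT, 709 in R320*) and NEAT1 (803 and 1136), LINC02476 (600 and 574) and LMAN1 (540 and 461). All connections of LMAN1, a protein-coding gene, were trans, with 0 local and 0 cis in either genotype. It gave 305 of the 2524 shared trans connections. Why its RNA was not listed at its own gene was not tested, so its numbers are uncertain.

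**Figure D2:**
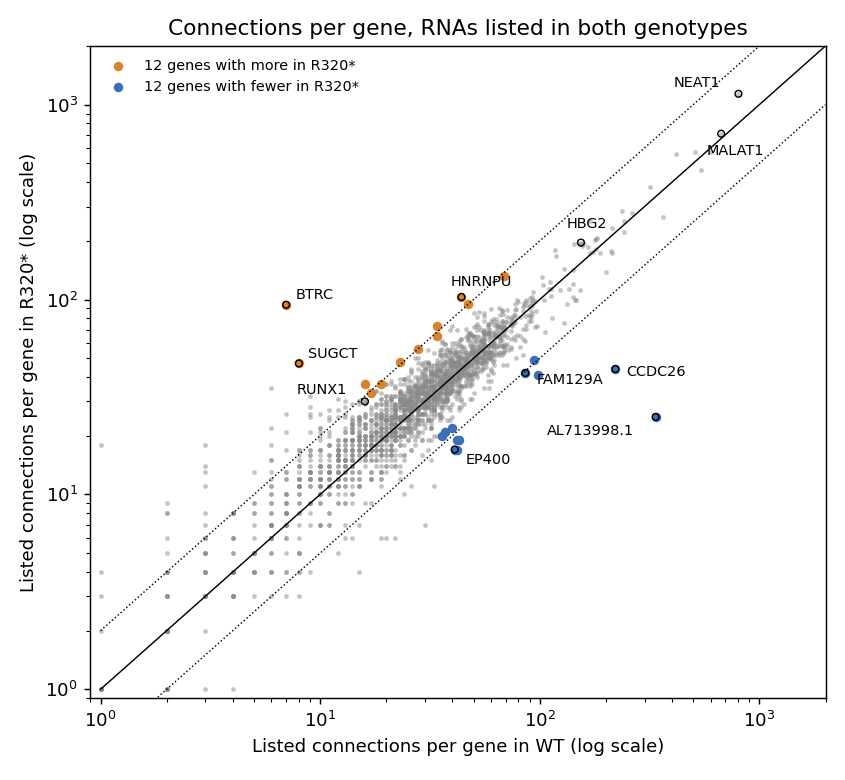
Each point is an RNA listed in both genotypes, by its number of listed connections in WT (x axis, log scale) and R320* (y axis, log scale); coloured points are the 12 genes with the largest ratio per direction, the solid line marks equal numbers and the dotted lines 2-fold. Most RNAs lie between the dotted lines, while BTRC (7 and 94) and AL713998.1 (337 and 25) lie far outside.

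A further 500 RNAs were listed in 1 genotype only. Of these, 273 were in WT only, 70 of them from chromosome 12, and 227 in R320* only, 3 of them from chromosome 12. The ones with most connections, named after their values were seen, were NYAP2 (404) and AC099520.1 (337) in WT, and AC011246.1 (82) and ELP4 (76) in R320*. For RNAs listed in both genotypes, 99.2% of local connections were shared.

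Erythroid genes as a group had more connections in R320*. Of 13 measured members of 47, 11 had more, 1 had fewer (the transferrin receptor TFRC, 47 and 46) and 1 was in R320* only (ERMAP, 22). Members with a higher number included the mitochondrial iron importer SLC25A37 (23 and 34), the transcription factor gene LMO2 (37 and 48) and the ankyrin gene ANK1 (33 and 42). The median log2 ratio was 0.34, at percentile 98.98 of random lists matched on connection number but not on chromosome. Scores of their shared connections did not go the same way: the median over members was -0.00458, at percentile 1.95. Over all their shared connections the median was 0.0011, against 0.0394 in the whole table. SLC25A37 and ANK1 lie on chromosome 8 and LMO2 on chromosome 11, with net cis shares (R320* only minus WT only) of 14.2% and 16.4%. Of the other members with more connections, only the globins below lie on these chromosomes. The fetal and embryonic globins HBG2 (154 and 196) and HBE1 (152 and 192), named after their values were seen, lie side by side on chromosome 11, and HBG2 is nearly identical to HBG1, so its value is uncertain. The numbers of these globins are nearly equal, so the pair may not be separate findings. Their cis numbers were the same in WT and R320* (85 for HBG2, 88 for HBE1), and the rise was in trans (66 and 108, 62 and 102). Without HBG2 and HBE1 the median was 0.29, at percentile 95.64.

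Stem and progenitor genes had a median log2 ratio of 0.38 at percentile 96.18, with 5 of 8 measured members higher in number, 1 lower, 1 equal and CD44 in WT only (4). LIN28B had 26 and 44 connections, IGF2BP1 46 and 64, and LMO2 37 and 48; LMO2 is in the erythroid list too. Nuclear long noncoding RNAs had a median of 0.46 at percentile 99.56, with 6 members of 9 higher in number, 2 lower and MIR17HG in R320* only (33). The leading members were GAS5 (8 and 17), MEG3 (36 and 20), SNHG1 (3 and 5) and PVT1 (46 and 71). With the minimum applied, that median was 0.25 at percentile 91.22, and by score difference the list lay at percentile 56.39.

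Megakaryocytic genes had a median log2 ratio of -0.07 at percentile 15.82. Of 9 measured members, 1 had more, 3 fewer, 1 the same number, 3 were in WT only and 1 in R320* only. The focal adhesion gene VCL had 37 and 30 connections, the myosin gene MYH10 28 and 32, ANGPT1 14 and 13, and MYH9 21 and 20. ETV6 (25, chromosome 12), ITGB1 (5) and FYB1 (2) were in WT only, and CD36 (2) in R320* only.

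RUNX1 and its partners had a median log2 ratio of 0.06 at percentile 43.68, with 7 of 13 measured members higher in number, 5 lower and 1 equal. Besides RUNX1 these included RUNX2 (6 and 3), the corepressor gene CBFA2T2 (37 and 48) and the histone methyltransferase gene KMT2A (60 and 50). Known RUNX1 targets had a median of 0.08 at percentile 40.98 (0.23 at 78.42 with the minimum applied) but a mean of -0.17, with 4 of 8 higher in number, 3 lower and 1 equal. The phosphatase gene PTPRJ had 30 and 7 connections, LMO2 37 and 48, MYB 24 and 29, and MYH10 28 and 32; most members of this list stand in other lists too. Taking each member's median score difference and then the median over members, both lists lay low among random lists. RUNX1 and partners came to -0.00762 (percentile 1.67), and known targets to -0.0321 (percentile 0.79). Over all shared connections of the list, however, the median was 0.0466 for RUNX1 and partners, above the 0.0394 of the whole table. For known targets it was -0.00421.

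Signalling genes had a median log2 ratio of 0.07 at percentile 38.49, or 0.18 at percentile 89.99 with the minimum applied. Of 19 measured, 9 had more, 7 fewer and 1 the same number, with GRB2 (44) and STAT5A (4) in WT only. The kinase gene LYN had 32 and 46 connections, STAT5B 58 and 75, and BCR 34 and 43. Chromatin and looping genes had a median of 0.04 at percentile 35.66 and a mean of -0.05, with 7 higher in number and 6 lower of 18 measured. CHD7 had 29 and 46 connections, KMT2C 106 and 68, MED13L (chromosome 12) 86 and 61, and EZH2 97 and 73. KDM6A (29), TET2 (18) and KMT2D (8, chromosome 12) were in WT only, and the DNA methyltransferase genes DNMT1 (22) and DNMT3A (14) in R320* only.

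Cell cycle and growth genes had a median of 0.02 at percentile 36.6. CDK6 had 65 and 73 connections, CCND3 19 and 17, E2F3 75 and 76, and MDM2 (chromosome 12) 30 in WT only. Of the lymphoid list, LEF1 had 15 and 24 and ZAP70 12 in R320* only. Of the non-blood list RBFOX3 had 1 and 1. Of the myeloid and ribosomal protein lists, 0 members were measured as RNAs.

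At the level of elements, single promoters and enhancers differed in how many RNAs they met. A promoter at LCP2, a haematopoietic signalling adaptor gene (chromosome 5, 170296312 to 170298082), met 16 RNAs in WT and 1 in R320*. Among the 16, AC099520.1, AC091987.1 and AC110614.1 had no connection to any element in R320*. An enhancer and a promoter at the interleukin-18 receptor gene IL18RAP (chromosome 2, 102413602 to 102414450 and 102417715 to 102420683) each met 9 and 1. Both met the same 9 RNAs, so the pair cannot be counted as separate findings. An enhancer near PCLO (chromosome 7, 83212944 to 83213226) met 1 in WT and 9 in R320*. A promoter of MRPL23-AS1 (chromosome 11, 1987949 to 1989500) and an enhancer inside CMC2 (chromosome 16, 80992810 to 80997692) each met 1 and 7, a ratio shared by 9 elements.

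Of 17481 elements with a mean of at least 2 RNAs and listed in both genotypes, 2159 met at least 2-fold more RNAs in R320* and 1679 at least 2-fold fewer. Of the latter, 344 lay on chromosome 12, which held 628 of the elements compared, against 5 of those with more. The kept elements had a median mean of 3 RNAs, so most such ratios rest on a few connections. Counting only RNAs listed in both genotypes, 1751 elements met at least 2-fold more in R320* and 1073 at least 2-fold fewer. The MALAT1 promoter met the most RNAs in both genotypes, 190 in WT and 187 in R320*.

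Chromosome 12 stood apart from all other chromosomes. Of 4434 connections onto it, 2635 were in WT only and 444 in R320* only, a net share (R320* only minus WT only) of -49.4%. The net share was -48.5% for cis and -53.3% for trans contacts. Over RNAs listed in both genotypes it was -12.9% and -50.1%. In cis contacts alone, over all RNAs, 11 of its 12 windows of 10 Mb had a net loss, against 44 of 216 elsewhere. The window from 0 to 10 Mb had a net gain of 17.6% in cis (34 R320* only, 16 WT only), but 13 and 33 in trans. Connections listed in both genotypes had a median score difference of 0.0195 over the whole of chromosome 12. Other chromosomes with a high net share were 18 (28.4%), 20 (18.5%) and 8 (12.4%), and chromosome X had -21.7% of 300 connections. On chromosome 8 the window from 120 to 130 Mb held 283 R320*-only and 45 WT-only cis connections.

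**Figure D3:**
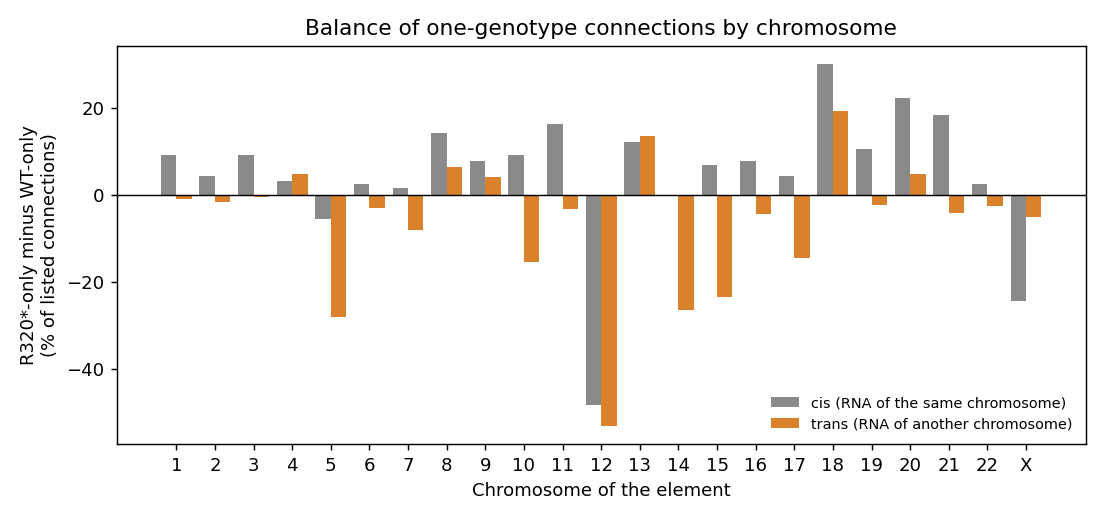
Bars give, for the elements of each chromosome (x axis), R320*-only minus WT-only connections as a percent of those listed (y axis), separately for RNAs of the same chromosome (cis) and of another (trans). Chromosome 12 is the lowest in both, at -48.5% and -53.3%.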

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

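Leaving out chromosome 12, the element blocks, the bound, zero, summed score, shared-RNA, SD margin, merging and one-genotype settings were chosen after the data were seen. No paired analysis was possible because the deposited values are pooled per genotype; for the same reason the replicate, count model, pseudocount and camera alternatives were not run. Counts were called close within 1.5 times and medians within their order-statistic interval. Lists by score difference were called close on the same side of the central 95% of random lists. By these rules 81 alternatives were close, 47 moved and 3 reversed. For the megakaryocytic, stem and progenitor, known target, cell cycle and nuclear noncoding RNA lists, the interval is the whole range of members. For known targets it runs from -2.10 to 0.376, so close says little for these lists. Single connections without the minimum could not differ, because every connection listed in both genotypes passed it. Centring likewise left the element counts unchanged. Of 58 alternatives of list and distance medians, 15 changed sign, 10 of them among the close ones, all lists near 0 (RUNX1 partners, RUNX1 targets, signalling, cell cycle, chromatin). The cause was not tested except where the setting itself loosens or tightens a threshold. Reversed were the erythroid list by score difference (-0.00458 against 0.34 by number) and, on centring, distances under 100 kb (-0.0115) and over 1 Mb (-0.00964). By score difference, as medians over members, RUNX1 partners came to -0.00762, known targets to -0.0321 and nuclear noncoding RNA to 0.0438. Over all shared connections of each list the medians were 0.0466, -0.00421 and 0.0263, and 0.0011 for the erythroid list. The sign for RUNX1 partners and for erythroid genes thus depends on whether genes or connections are summarised.

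Counts below are R320* higher, then lower. Single connections (52 and 39) came to 38 and 49 centred, 1048 and 601 at the smaller difference set in place of 1.5-fold, 0 and 4 at 2 units, 1709 and 1465 with one-genotype connections at their bound, and 32955 and 30404 with 0 taken as 0. Genes (8 and 8) came to 70 and 35 at 1.5-fold, 2 and 2 at 4-fold, 72 and 34 without a minimum, 4 and 5 on the same chromosome, 5 and 5 by summed score, 36 and 19 on the second block, and 20 and 26 with one-genotype genes. Centring left 5 genes with more, and leaving out chromosome 12 left 5 with fewer. Elements (2159 and 1679) came to 4319 and 3427 at 1.5-fold, 319 and 292 at 4-fold, and 4061 and 3387 without a minimum, and 1073 had fewer among RNAs of both genotypes.

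Connections in R320* only and WT only (32903 and 30365) came to 10952 and 10981 on the second block (16958 in both), 19518 and 18353 past an SD margin, and 8072 and 8462 when merged by RNA in 1 Mb (9444 in both); the first block had 19384 in WT only. Merging turns the balance to WT, while on the second block the numbers were nearly equal. From 100 kb to 1 Mb the median difference was 0.0183 centred and 0.0654 above the median score; over 1 Mb it was 0.0537 above the median score; on other chromosomes it was -0.0435 centred. Pooling leaves depth unknown, so contacts missed at low depth cannot be separated from absent ones.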

Other observations

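The tests of chromosome 12, of the balance between chromosomes, of one-by-one crossing and of gene shut-off were chosen after the result was seen; those of a minimum per RNA, of score spread and of random trans placement were written before.

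The trans contacts most often listed in both genotypes joined the loci of the Philadelphia rearrangement, which in K562 fuses BCR on chromosome 22 to ABL1 on chromosome 9. Of 300 connections from chromosome 9 RNAs to chromosome 22 elements, 75.7% were in both genotypes, the highest of 61 chromosome pairs with at least 100 connections (median 8.40%, next highest 49.6%, from chromosome 22 to 9). ABL1 gave 142 of them, 126 in both genotypes, and its neighbour NUP214 gave 127, 97 in both. On chromosome 13, ABL1 contacted 27 elements, 26 of them in both genotypes, and NUP214 27, all in both, within 80591847 to 108007474. Trans contacts onto chromosome 22 between 15 and 25 Mb numbered 2138, of which 29.9% were in both.

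From chromosome 5 to chromosome 8, 0 of 243 connections were in both genotypes, with 200 in WT only and 43 in R320* only. It was 1 of 4 pairs among the 61 with none in both; the others were 2 to 1 (125 connections), 8 to 1 (116) and 8 to 6 (103). AC099520.1 gave 89 of the WT-only ones, LINC02163 60 and AC091987.1 33; AC099520.1 and AC091987.1 had no connection at all in R320* and so could not be shared. Over RNAs of both genotypes, 0 of 121 were shared, with 78 in WT only and 43 in R320* only. Chromosome 8 took 14.9% of the 1343 trans connections of chromosome 5 RNAs in WT and 5.36% of 802 in R320* (7.82% and 5.42% over RNAs of both genotypes), against 4.50% of the elements outside chromosome 5. Distal chromosome 8 (beyond 120 Mb) had 284 trans connections in R320* only and 75 in WT only, and 381 and 106 in cis. These regions were picked after their values were seen.

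Chromosome 12 had far more WT-only than R320*-only connections. RNAs absent from the R320* table held most of the cis loss: of 2011 WT-only cis connections, 528 belonged to RNAs of both genotypes. Their absence as the whole cause is argued against. Over RNAs of both genotypes the net cis share was -12.9%, against -48.5% over all RNAs, and still below the range elsewhere of -1.05% to 18.6%. Fewer copies of chromosome 12 in the R320* cells may account for it, since RNAs of other chromosomes also had fewer contacts there (net trans share -53.3%, elsewhere -28.2% to 19.3%). Over the other 22 chromosomes net cis and trans shares went together (Spearman's rho 0.558, two-sided permutation p 0.00780). Pearson's r was 0.506 (two-sided permutation p 0.0165). Without chromosomes X and 18, rho was 0.468 and r 0.557. Copy differences between the cells would give this, but both shares are counted at the same elements. Any change acting on those elements would give it too, so the correlation cannot single out copy number. The net cis gain at 0 to 10 Mb and the near-equal shared scores are not accounted for, no copy number was measured, and an effect of RUNX1 R320* stays open and untested, because genotype and cell population coincide.

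Another 500 RNAs had all of their connections in 1 genotype. Connections crossing the score minimum one by one are argued against: of 1630 RNAs with at least 20 WT connections, 125 had 0 left in R320* and 8 had up to 20% left. A minimum applied per RNA, near which the RNA itself lies, may account for part of it, since WT-only RNAs had a median of 18 connections against 28 for RNAs of both genotypes, and R320*-only RNAs 20 against 30; their median local scores were not lower, though (2.56 against 2.39 in WT). Whether genes were shut off stays open: 5 of 47 listed housekeeping genes (10.6%, Wilson 95% interval 4.63% to 22.6%) were in 1 genotype only, against 19.0% of all RNAs, after leaving out 14 genes whose values had been seen when the list was drawn up; with these it was 11 of 60 (18.3%). An effect of the RUNX1 genotype on these RNAs stays open and untested.

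Most cis connections over 1 Mb and most trans connections were in 1 genotype only. A score spread like that of high-scoring shared connections is argued against as the sole source, over RNAs of both genotypes. Of 25012 WT cis connections more than 3 SD above the minimum (SD 0.199, from shared connections with a WT score of at least 2.5), 8.92% had no R320* score. Of 2066 such trans connections (SD 0.310) 62.7% had none. The cis cut may be too low: the SD over all shared cis connections was 0.254, and connections missing from R320* enter neither SD. Trans contacts placed at random, with every element equally likely, are also argued against. Of them 2524 were shared against 88.0 under such independent placement of each RNA, a ratio of 28.7. It was 22.1 without the RNAs and elements of chromosomes 9, 13 and 22, and 18.4 without the elements at 65 to 66 Mb of chromosome 11 (MALAT1 and NEAT1) as well. Elements differ in length and in how many RNAs they meet, and random placement weighted by these was not tested. Shallow sampling of true but rare contacts could leave such a picture and was not tested, because the depth is unknown. Differences between cultures and an effect of RUNX1 R320* stay open for the same connections.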
